A study of Homo sapiens with 8 samples.

How the data were processed

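Total RNA was extracted from the cells with TRIzol and made into libraries with a small RNA library kit, per the labels' protocols. Library fragments of 160 to 220 base pairs were selected, per the labels. The 8 deposited samples are 4 libraries with 2 sequencing lanes each, since both lanes of a replicate carry the same library code in the labels. The deposited table has 1 column of counts per library code and no separate lanes. Whether the authors summed the lanes is not given in the sources used here. The columns were matched to groups through these codes, and 0 count columns were left without a group.

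The deposited values are whole-number counts of reads per tRNA gene, without normalization by the authors as far as the values show. Bowtie2 2.2.2 and the builds hg38 and GRCh38 are named in the submitters' processing notes, and the labels name summarizeOverlaps. How reads with several matches, mismatches at modified bases, or strand were handled is not given in the sources used here. This matters for tRNAs, since many genes have near-identical copies and since inosine is read as guanosine, so an edited tRNA differs from the genome at the edited base. The table also gives an intron flag and a whole number headed mismatch, whose meaning is not stated, for each gene, as deposited by the authors. The tRNA gene prediction score of each gene is as deposited, per the file headers, and how the authors made it is not stated. The table names each gene with its amino acid and anticodon. For 26 genes the name disagrees with the amino acid or anticodon columns, and the columns were used. Gene positions were compared with GENCODE v29, where 396 genes lay between annotated genes, 190 in introns, 43 overlapped an exon and 2 were on a scaffold. Of the 631 genes, 424 matched a RefSeq tRNA gene at both ends. No genome sequence was used here, so copies were grouped by the number in the gene symbol, which gave 465 groups, 59 of them with more than 1 gene. Joining groups through RefSeq symbol numbers gave 458.

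Counts were tested with edgeR 4.0.16 (R 4.3.3) at the level of genes, of anticodon families and of identical copies. Genes were kept by filterByExpr with a minimum count of 10, library sizes were scaled by TMM at each level, and the quasi-likelihood test compared the 2 knockdown with the 2 control libraries. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. SEs of log2 fold changes are the fold change divided by the root of the F statistic. Ratios within a replicate number are ratios of TMM-scaled counts after 0.5 was added to each count. They come from 1 library per group and so have no error of their own. Lists were tested with camera of limma 3.58.1, with its preset correlation of 0.01 and with an estimated one, and with fry, for lists of at least 3 tested genes. The lists were the 8 A34 families, the same amino acids with other anticodons, the other amino acids, common sources of tRNA fragments cleaved at the anticodon, queuosine anticodons, intron-containing families, initiator genes, rare anticodons with A at position 34 and Arg-TCT-4-1. limma's fry asks whether the genes of a list move, on balance, in a common direction. For the A34 genes it gave an adjusted p of 0.987 over all libraries and 0.551 with the replicate number as a term. Shares of counts were compared by an exact permutation test, and single shares carry 95% Wilson intervals (scipy 1.17.1). A gene without a count in a library could hold up to 3 counts, or 4.30 and 2.80 CPM in control libraries 3 and 4 and 3.41 and 2.48 CPM in the knockdown libraries.

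The design over all 4 libraries without a further term, the lists, the named items and the alternatives were set before the data were examined. The labels do not say that a replicate number marks a batch. The table showed that same-numbered libraries deviated from their group means together (correlation 0.935 across genes), so values within each number were added beside the results over all libraries. The fit with the number as a term was among the alternatives set beforehand, and its variants with other scalings, filters and DESeq2 1.42.0 were added after the data were seen. Items were named by rule. These were the 8 A34 families with the gene of most control counts in each, the 10 genes with the highest mean control CPM, Arg-TCT-4-1 and iMet. Genes, families and groups that passed were to be named. With fewer than 5 calls, the 10 genes and groups and the 6 families with the smallest p were given as values. Genes called with the number as a term were named by a rule made after the data were seen.

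The tests were checked on counts simulated with the real gene means per replicate number and the real library sizes. Each level had 1 common dispersion, 0.0178 for genes, taken from the fit with the number as a term. Genes were drawn independently. The simulations therefore follow that fit's assumptions, without correlation between genes, and cannot check them. Of 480 simulated genes 198 were changed by 2-fold or 4-fold. In 20 simulations without change, the fit with the number as a term made a median of 0 and at most 2 calls at gene level. A list changed by 1.5-fold was called by camera's preset correlation in 20 of 20 draws, with and without the term. With an estimated correlation it was called in 20 of 20 draws without the term and 10 of 20 with it. Alternatives covered DESeq2 size factors, library totals, TMM from genes outside the A34 families, other count filters, DESeq2, the replicate number as a term and each library left out. Figures were drawn with matplotlib 3.10.9.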

Results

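Small RNA libraries were compared between 2 lines of HEK293T cells, a human embryonic kidney line. ADAT2 is a subunit of the heterodimeric adenosine deaminase that turns the adenosine at anticodon position 34 of certain tRNAs into inosine. The edited line carried a CRISPR/Cas9 change in ADAT2 and is labelled with 50% of normal ADAT2 expression. The control line received a Cas9 plasmid without a guide and is labelled with 100%. Each group held 2 libraries, which carry the replicate numbers 3 and 4 in both groups. The deposited table gives a read count for 631 tRNA genes in each of the 4 libraries. Total counts were 698143 and 1069932 in control libraries 3 and 4, and 878791 and 1211292 in knockdown libraries 3 and 4. In all, 57 genes had no count in any library. ADAT2 is not a tRNA gene, so its own level cannot be read from this table and the labelled expression was not checked. The labels do not say whether the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The groups set the edited line against the control line. An effect of ADAT2 therefore cannot be told apart from other differences between the lines.

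The first question, posed by the series title, was how unequally tRNA genes contribute to the reads. Read shares are not levels of expression, since how well each tRNA entered the libraries was not measured. The counts also do not separate whole tRNAs, precursors and fragments. In the control libraries the Gly-CCC family gave 14.3 ± 6.04% of counts, Gly-GCC 12.7 ± 3.65%, Val-CAC 9.20 ± 5.42% and Glu-CTC 6.07 ± 2.13% (mean ± SD, n = 2). By the amino acid column of the deposited table, these 4 families carry glycine, valine and glutamate. Gly-CAC-chr1-17 gave 27.3% of the control counts of Val-CAC. It is among the 26 genes whose name disagrees with the columns. In control libraries 3 and 4, 123 and 164 genes were enough to give 90% of the counts. In knockdown libraries 3 and 4 this took 122 and 174 genes. The group means were 143.5 ± 28.99 and 148 ± 36.77 genes (SD, n = 2), so the groups differed by less than the spread between their libraries. The 10 most abundant genes gave 34.5% and 24.9% of counts in the controls, and 35.7% and 21.7% in the knockdown libraries, for numbers 3 and 4.

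**Figure D1:**
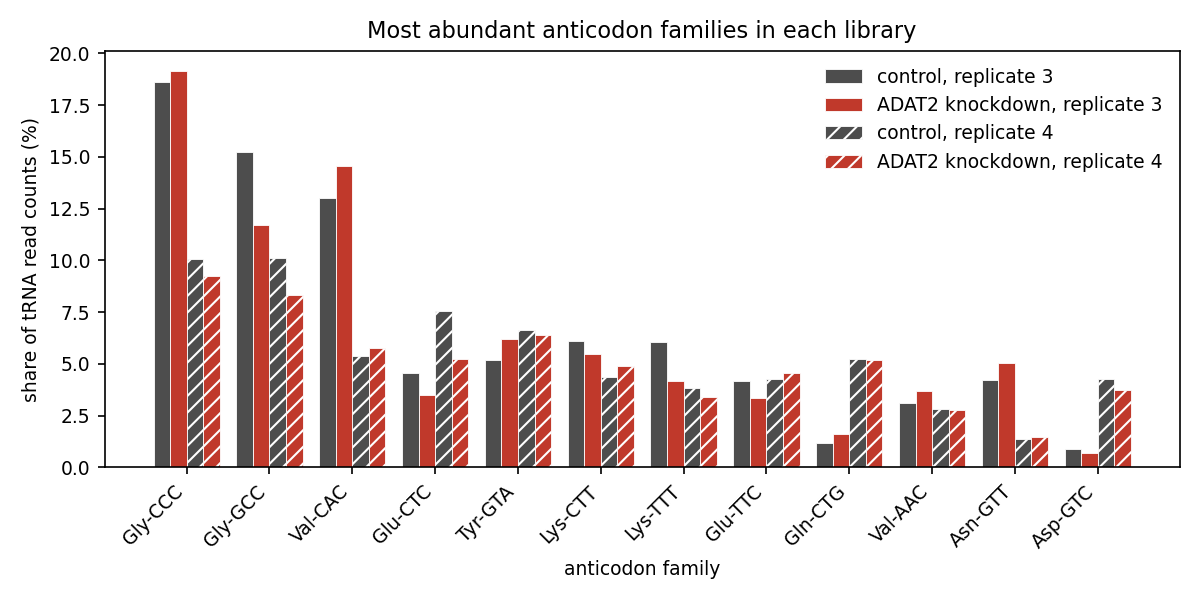
Share of tRNA read counts (%) taken by the 12 anticodon families with the highest mean control share, with 1 bar per library (grey, control; red, ADAT2 knockdown; hatched, replicate number 4). Gly-CCC took 18.6% and 19.2% in control and knockdown library 3, and 10.1% and 9.26% in library 4.

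The gene with the highest mean over the control libraries was Gly-CCC-chr1-137 on chromosome 1 (16545939 to 16546009, hg38, intergenic in GENCODE v29), at 59347 ± 28820 CPM (counts scaled to a common library total; SD, n = 2). Its sister copy Gly-CCC-1-2, within an intron of CROCC on the same chromosome (16861921 to 16861991), had 46577 ± 16578 CPM. Gly-CAC-chr1-17 and Val-CAC-8-1, both counted in the Val-CAC family, followed at 26062 ± 21318 and 25838 ± 21179 CPM. Their counts lay close to each other in every library, such as 28719 and 28494 in control library 3. Gly-GCC-1-5 on chromosome 21 had 25433 ± 10678 CPM, Glu-CTC-2-1 23559 ± 21946 and Gln-CTG-4-1 18359 ± 21495. In control library 4 alone Glu-CTC-2-1 had the most counts, 41810 against 41693 for Gly-CCC-chr1-137. Glu-TTC-2-1 had 17725 ± 327 CPM, Lys-TTT-3-1 14907 ± 3546 and nm-tRNA-Tyr-GTA-chr14-8, in an intron of AKAP6, 14880 ± 16978. The last of these matched no RefSeq tRNA gene, and its nm prefix is not explained in the sources used here. Whether its reads came from this locus or from a similar tRNA elsewhere was not tested. For Gln-CTG-4-1 and nm-tRNA-Tyr-GTA-chr14-8 the SD between the control libraries exceeded the mean. None of the 10 passed the test between groups, either without or with the replicate number as a term. Reads from identical copies cannot be told apart by sequence. How reads that match several near-identical copies were assigned is not given, so the split of counts among such copies is uncertain.

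The replicate number separated the libraries more than the group did. Across 489 genes with enough counts, edgeR's quasi-likelihood test with the group as a second term called 197 genes higher and 183 lower in number 4 than in number 3 (Benjamini-Hochberg adjusted p under 0.05). At the level of anticodon families it called 18 higher and 12 lower of 52. Leu-CAG was higher in number 4 by 2.27 ± 0.08 and Ala-CGC by 2.29 ± 0.15 on the log2 scale (SE, 2 libraries per number). Asn-GTT fell by 2.11 ± 0.08 and Gly-CCC fell by 1.37 ± 0.08 in number 4. The first principal component of the log2 CPM values held 90.4% of the variance and separated the numbers. The second held 6.76% and separated knockdown from control in both numbers. For this reason many comparisons below give the ratio of knockdown to control within number 3 and within number 4 beside the result over all 4 libraries. Some genes and groups are given by part of these values only, or by the fit with the number as a term. Over all 4 libraries 0 of the 489 genes passed between groups.

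The main question was whether the tRNAs that carry inosine at position 34 differed between the lines. These are the 8 families with an A at that position that ADAT edits, namely Ala-AGC, Arg-ACG, Ile-AAT, Leu-AAG, Pro-AGG, Ser-AGA, Thr-AGT and Val-AAC. Together they took 8.21% of counts in control library 3 (95% Wilson interval 8.14 to 8.27) and 10.8% in knockdown library 3 (10.8 to 10.9). In number 4 they took 10.4% in the control (10.3 to 10.5) and 12.9% in the knockdown library (12.8 to 12.9). The knockdown libraries were therefore higher by 2.64 and 2.48 percentage points within numbers 3 and 4. The other anticodons of the same 8 amino acids were higher by 2.85 and 2.02 points. They took 20.7% and 24.5% in control libraries 3 and 4, against 23.5% and 26.5% in knockdown (two-sided exact permutation p = 0.667). Relative to their larger control share, this was a smaller rise than that of the A34 families. Over all libraries the A34 share was 9.30 ± 1.55% in control and 11.9 ± 1.44% in knockdown cells (SD, n = 2). Both knockdown libraries lay above both controls, which gave a two-sided exact permutation p of 0.333, the smallest that 2 against 2 libraries allow. The intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The rise within a number stayed between 1.32 and 2.82 percentage points when any 1 of the 8 families was left out.

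**Figure D2:**
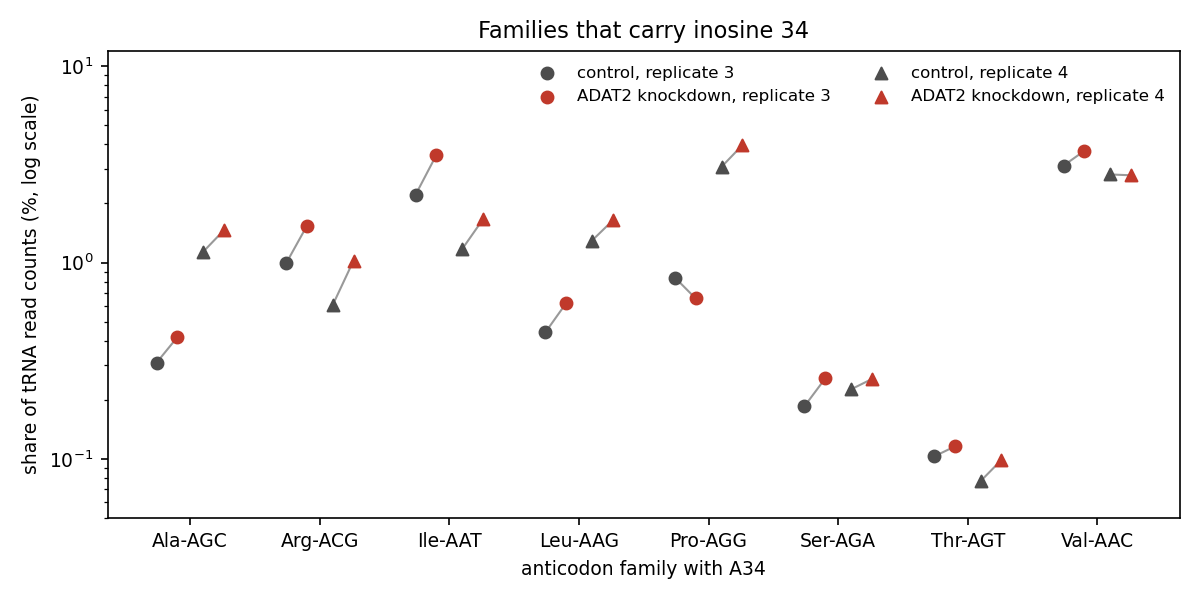
Share of tRNA read counts (%, log scale) of the 8 A34 families in each library, with circles for replicate number 3, triangles for number 4, and grey lines joining the control (grey) and ADAT2 knockdown (red) library of a number. The share is higher in knockdown in both numbers for 6 of 8 families, all but Pro-AGG and Val-AAC, and for 5 of 8 with gene-level TMM factors in place of library totals.

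Among the 8 families, Arg-ACG took 0.990% and 0.608% of counts in control libraries 3 and 4, against 1.54% and 1.02% in the knockdown libraries. With family-level TMM factors, its log2 ratio of knockdown to control was 0.52 in number 3 and 0.90 in number 4. Ile-AAT had log2 ratios of 0.56 and 0.65, Leu-AAG of 0.38 and 0.49, and Ala-AGC of 0.32 and 0.52. Ser-AGA had ratios of 0.36 and 0.32, Thr-AGT of 0.06 and 0.51, and Val-AAC of 0.14 and 0.14. Pro-AGG differed in direction between numbers, with −0.46 in number 3 and 0.52 in number 4. Ala-AGC, Arg-ACG, Ile-AAT, Leu-AAG and Thr-AGT were higher in both numbers under each of the 8 sets of scaling factors tried. Ser-AGA was lower in number 4 with gene-level TMM factors, and Val-AAC was lower in number 4 under all sets except the family-level TMM factors used here. The median log2 ratio of all families ran from −0.14 to 0.27 with the number and set of factors, so single ratios carry a shift of that size. In number 4 the family-level TMM factors used here gave the 0.27, and gene-level TMM factors the −0.14. With the latter, number 4 ratios were 0.49 for Arg-ACG, 0.24 for Ile-AAT, 0.10 for Ala-AGC and 0.08 for Leu-AAG. In number 3 they gave higher ratios, such as 0.71 for Arg-ACG.

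None of the 52 tested families passed the test between groups in edgeR's quasi-likelihood fit over all 4 libraries. The count at an unadjusted p under 0.05 was 0, DESeq2 called 0 of 56, and adjustment over the list of 8 alone gave 0. With the replicate number as a term 0 families passed, 11 had an unadjusted p under 0.05 and the smallest Benjamini-Hochberg adjusted p was 0.202. With library totals in place of TMM that fit called 5 families higher, 2 of them A34 families, and 5 of the 8 A34 families passed when adjusted over the list alone. Beside 1 residual degree of freedom, edgeR's prior degrees of freedom were 1.21 with TMM and infinite with library totals. The fit with TMM therefore had few degrees of freedom with which to call a family. Counts were simulated with this spread between numbers, under the assumptions of the fit with that term. On them the fit without that term recovered 0% of families changed by 2-fold or 4-fold. The fit with it recovered 30% and 100%. The 6 families with the smallest p over all libraries, as values, included Ser-AGA and Arg-ACG. The others were elongator Met-CAT (log2 ratios 0.50 and 0.63 in numbers 3 and 4), Ser-TGA (0.72 and 0.39, but −0.02 in number 4 with gene-level TMM factors), Thr-CGT (0.42 and 0.61) and Cys-GCA (0.07 and 0.81). Initiator iMet-CAT, which starts translation, had ratios of −0.49 and 0.10, and was lower in number 4 as well under the 7 other sets of scaling factors.

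At the level of single genes, edgeR's quasi-likelihood test over all 4 libraries called 0 of 489 genes at an adjusted p under 0.05. DESeq2 called 0 of 574. Only 1 gene had an unadjusted p under 0.05. With the replicate number as a term, a replicate block, 39 genes passed, 26 of them higher and 13 lower in knockdown cells. Among them Ala-AGC-2-1 had opposite directions in the numbers, with log2 ratios of −0.62 and 2.28. That fit leaves 1 residual degree of freedom and borrows its spread from all genes. On counts simulated under the assumptions of the fit with the term, the fit without it recovered 0% of genes changed by 2-fold or 4-fold. The fit with the term recovered 93% and 100%, with 5 false calls. Calls numbered 24 to 76 under other scalings, filters and DESeq2 with the same term, and 12 of the 39 passed under all of them.

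Genes from several anticodon families rose within both numbers. Met-CAT-5-1, an elongator methionine tRNA gene on chromosome 6 (26701483 to 26701555, hg38, intergenic), had 74 and 117 counts in control libraries 3 and 4 against 475 and 443 in the knockdown libraries. It was the gene with the smallest p over all libraries, with a log2 fold change of 2.06 ± 0.65 (SE, n = 2 per group; edgeR adjusted p = 0.998). With the number as a term it rose by 1.93 ± 0.21 (edgeR adjusted p = 2.37e-16). Over the other 6 settings of that fit the rise was 1.98 to 2.04 and the adjusted p ran from 4.28e-21 to 0.000471, the latter with TMM from genes outside the A34 families, where edgeR's prior degrees of freedom were 9.23 and not infinite. Met-CAT-chr6-167, a copy 98630 bases away (26800113 to 26800185), rose by 1.32 ± 0.19, with ratios of 1.45 and 1.19 in numbers 3 and 4. Asn-GTT-10-1 on chromosome 1 (145129239 to 145129312) rose by 1.37 ± 0.19, with ratios of 1.74 and 0.98. The copies Ala-AGC-9-1 and Ala-AGC-9-2, both on chromosome 6 and both A34 genes, rose by 1.14 ± 0.19 and 1.15 ± 0.19. Glu-CTC-3-1 on chromosome 13 rose by 0.99 ± 0.19, Arg-TCG-6-1, in an intron of C9orf152 on chromosome 9, by 0.97 ± 0.26 and Thr-AGT-3-1 on chromosome 6 by 0.96 ± 0.29. These 8 genes had the largest rises among called genes with a mean of at least 50 counts and 1 direction in both numbers, a choice made after the values were seen. Of the 8, 6 passed under all 7 settings of the fit with the number as a term, and Arg-TCG-6-1 and Thr-AGT-3-1 lost their call with DESeq2.

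By the same later choice, the 8 genes with the largest falls were named. Over all libraries each of them had an edgeR adjusted p of 0.998. Only Gly-CCC-7-1 of these passed under all 7 settings, and the other 7 lost their call in at least 1 setting, Cys-GCA-2-3 in 5. With TMM and the number as a term, Leu-TAA-2-1 fell by 0.88 ± 0.27 on the log2 scale, Lys-TTT-5-1 by 0.76 ± 0.24 and Gly-CCC-7-1, in an intron of GREB1, by 0.73 ± 0.19. Cys-GCA-2-3 decreased by 0.72 ± 0.24 and Asp-GTC-2-3 by 0.71 ± 0.19. Phe-GAA-1-5 decreased by 0.68 ± 0.19, Ser-AGA-2-5 by 0.68 ± 0.22 and Val-TAC-1-2 by 0.67 ± 0.18. Across the 411 genes with a mean of at least 50 counts, the log2 ratios of numbers 3 and 4 had a Pearson r of 0.529 and a Spearman rho of 0.498. Both permutation p-values were 1e-05, the smallest 100000 permutations give, and 1e-05 after adjustment over the 6 sets of genes or families tested. Without the 2 most extreme genes r was 0.570. This was the highest r of the 6 sets. All 489 tested genes gave an r of 0.331 and a rho of 0.391. The 52 families gave an r of 0.0268 (permutation p = 0.849) and a rho of 0.353 (permutation p = 0.0103), with an r of 0.425 without the 2 most extreme. The 99 A34 genes gave an r of 0.227 (permutation p = 0.0247, adjusted 0.0296) and a rho of 0.190 (permutation p = 0.0604), with an r of 0.143 without the 2 most extreme, and 55 of them had the same sign in both numbers. These correlations are across genes or families, which are not independent replicates.

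**Figure D3:**
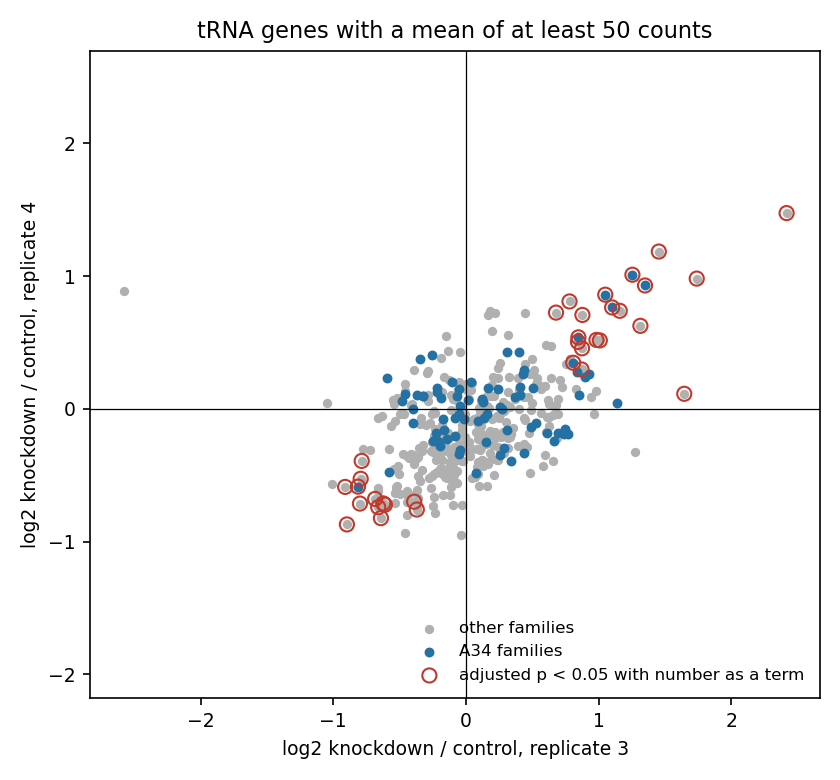
Log2 ratio of knockdown to control within replicate number 3 (horizontal axis) and number 4 (vertical axis) for the 411 tRNA genes with a mean of at least 50 counts, on the scale of gene-level TMM factors. Blue points are the 78 genes of the A34 families, grey points the other genes, and red rings the 33 genes drawn here that passed with the replicate number as a term; Met-CAT-5-1 lies at 2.42 and 1.48.

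The other genes among the 10 with the smallest p over all libraries are given as values. Thr-AGT-4-1 had log2 ratios of 1.68 and 1.47 in numbers 3 and 4 from 8 and 10 control counts. Ile-TAT-3-1 had ratios of 1.49 and 1.91, and Thr-AGT-3-1 of 1.05 and 0.86. Arg-TCG-4-1 and Ala-AGC-2-2 differed between numbers, with 1.64 against 0.11 and 0.19 against 2.16. Summing genes that share a number in their symbol, taken as copies of 1 mature sequence, gave 326 tested groups. Of these 0 passed over all libraries in edgeR, with 1 at an unadjusted p under 0.05, and DESeq2 called 0 of 409. With the replicate number as a term 45 passed, 33 higher and 12 lower. Genes named by chromosome stayed on their own in this grouping, although RefSeq symbols join 6 sets of them to other copies, Met-CAT-chr6-167 to Met-CAT-5-1 among them. With these joined, a grouping chosen after the data were seen, 0 of 319 groups passed over all libraries and 44 with the number as a term. Without this joining, the 45 calls fell to 0 when TMM factors were taken from groups outside the A34 families. The 10 groups with the smallest p were Met-CAT-5, Met-CAT-chr6-167, Thr-AGT-4, Asn-GTT-10, Asn-GTT-chr1-122, Thr-AGT-3, Arg-TCG-4, Ala-AGC-2, Arg-TCG-2 and Ala-AGC-9. Their log2 fold changes ran from 0.82 to 2.03, all with adjusted p = 0.999 (edgeR).

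Within each A34 family the gene with the most control counts was followed. Arg-ACG-1-1 on chromosome 6 (26328140 to 26328212, intergenic) gave 57.0% of its family's control counts. It had 3893 and 3759 counts in control libraries 3 and 4 and 9991 and 8668 in the knockdown libraries. With the number as a term it rose by 0.93 ± 0.28 (SE; edgeR adjusted p = 0.0188). Ser-AGA-5-1 on chromosome 7 rose by 0.70 ± 0.19 (edgeR adjusted p = 0.00758). The other 6 did not pass. Ile-AAT-2-1 had log2 ratios of 0.84 and 0.28 in numbers 3 and 4, Leu-AAG-1-2 of 0.90 and 0.24, and Ala-AGC-7-1 of 0.17 and 0.16. Val-AAC-3-1 had ratios of 0.69 and −0.18, Pro-AGG-2-6 of −0.07 and 0.10, and Thr-AGT-2-1 of −0.05 and −0.04. Of the 99 tested A34 genes, 9 rose and 1 fell with the number as a term, and 10 passed when adjusted over the list alone. If genes were independent, 5.26 of the 26 higher genes would lie in these families by chance (two-sided Fisher's exact p = 0.0770). Copies such as Ala-AGC-9-1 and Ala-AGC-9-2, both among the higher genes, may share reads. The test counts them as separate genes.

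As a group, 70 of the 99 A34 genes had a positive log2 fold change over all libraries, with a median of 0.11. With library totals in place of TMM 81 were higher, with a median of 0.26. The median was 0.76 without control library 4 and 0.40 without knockdown library 3. The camera test, which compares a list with all other genes, called them higher with its preset correlation (Benjamini-Hochberg adjusted p = 0.00218). The call was lost with an estimated correlation (adjusted p = 0.489). It was also lost without control library 3 (adjusted p = 0.961, with a median of −0.06 but a mean of 0.11) and without knockdown library 4 (adjusted p = 0.895), where 45 of 98 were higher, the median was −0.18 and the direction turned. With the number as a term 63 of 99 were higher, and the camera adjusted p was 0.00191 with the preset and 0.799 with an estimated correlation. The 8 families listed as common sources of tRNA fragments cleaved at the anticodon share Val-AAC with the A34 list. Of their 106 genes 31 had a positive log2 fold change, with a median of −0.20, and camera called them lower. Their camera adjusted p was 0.00218, and 0.493 with an estimated correlation. The preset call of this list, too, was lost without control library 3 or knockdown library 4 (adjusted p = 0.961 and 0.895), with medians of 0.03 and 0.06. In this list Gly-GCC took 15.3% and 10.1% of control counts in numbers 3 and 4, against 11.7% and 8.34% in knockdown. Glu-CTC took 4.57% and 7.58% in control, against 3.51% and 5.22%. Val-CAC took 13.0% and 5.37%, against 14.5% and 5.75%, and its direction in number 4 varied with the scaling. Gly-GCC, Glu-CTC and Asp-GTC were lower in both numbers under all 8 sets of scaling factors.

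At gene level the lists by amino acid, modification, intron and initiation did not pass camera over all libraries. Genes of the same 8 amino acids with other anticodons were higher in 51 of 130 (adjusted p = 0.658), but in 70 with DESeq2's size factors, in 82 with library totals and in 17 of 21 families. Genes of the other amino acids were higher in 107 of 256 (adjusted p = 0.107). Families read by queuosine-modified anticodons were higher in 31 of 66 genes (adjusted p = 0.782), intron-containing families in 20 of 33 (adjusted p = 0.246) and initiator genes in 2 of 9 (adjusted p = 0.107). At the level of families, camera called the A34 list higher (adjusted p = 0.0271) and the other amino acids lower (adjusted p = 0.0410), both with an adjusted p of 0.415 under an estimated correlation, and the fragment sources did not pass (adjusted p = 0.107). Split by the base at position 34, genes with A were higher in 72 of 101 (adjusted p = 0.00218, and 0.489 with an estimated correlation), and nearly all of them belong to the 8 families. Genes with C, G and T had adjusted p-values of 0.658, 0.837 and 0.0554, where genes with G had a median of 0.02 although camera ranked them lower. With the number as a term the last of these passed with the preset correlation (adjusted p = 0.0309, and 0.988 with an estimated correlation). Genes with A at position 34 outside the 8 families formed no list of at least 3 tested genes under the rarer anticodons listed. Arg-TCT-4-1, a gene known for its expression in the nervous system, had 1 count each in control and knockdown library 3, and 26 and 16 counts in library 4.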

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

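Fits that combine the replicate number with another setting, family or group fits with gene-level factors, list tests with library totals, and groups joined through RefSeq symbols were chosen after the data were seen. The counts of 0 genes, families and groups over all 4 libraries stayed at 0 under each scaling, filter, DESeq2 and each library left out. Lane 1 alone, lane 2 alone, lanes as separate samples and the comparison of lanes were not run, since the table does not separate lanes. The replicate block called 39 genes, 0 families and 45 groups. The labels do not tie the numbers to a batch, and with 2 numbers the correlation of 0.935 between same-numbered deviations is a hint from the data only. With the block, gene calls numbered 61 with DESeq2's size factors, 76 with library totals, 66 with a mean of at least 50 counts and 24 with DESeq2, where 134 genes had no adjusted p. Of the gene calls, 26 of 39 were higher in the main scaling, 53 of 76 with library totals and 27 of 31 with TMM from genes outside the A34 families. Family calls numbered 5 with library totals, 6 with TMM from outside the A34 families and 1 with DESeq2. Of these 2, 2 and 1 were A34 families. Group calls numbered 29 with DESeq2's size factors, 0 with TMM from outside the A34 families, 7 with a mean of at least 50 counts, 10 with DESeq2 and 25 with gene-level TMM factors. With DESeq2, 198 of 409 groups had no adjusted p. At family level edgeR's prior degrees of freedom were infinite in the fits with 5 and 6 calls. They were 1.21 with TMM, 1.44 with DESeq2's size factors, 1.195 without a count filter and 0.899 with a mean of at least 50 counts. These last fits each called 0 families. The settings thus differed in degrees of freedom as well as in scaling. The cause of the differences in calls was not tested. Median log2 fold changes of all genes moved from −0.03 with TMM to 0.11 with library totals.

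The number of lists called by camera was 3 over all libraries, 0 with an estimated correlation, and 0 to 6 with 1 library left out. Leaving out a library leaves 1 library in its group, assumed to vary like the other group, and unbalances the numbers. The sign of some log2 fold changes then turned: Ala-AGC −0.50 to 1.29, Cys-GCA −0.56 to 1.24, Ile-AAT −0.38 to 1.42, Leu-AAG −0.21 to 1.06, Pro-AGG −1.28 to 1.12, Thr-AGT −0.18 to 0.68, Thr-CGT −0.26 to 1.14, Val-AAC −0.40 to 0.44, the group Ala-AGC-2 −1.20 to 2.97 and the gene Ala-AGC-2-2 −0.73 to 2.95. The A34 share difference of 2.56 percentage points ran from 1.47 to 3.66 with 1 library left out, and was positive throughout.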

Other observations

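The tests of neighbouring genes and of identical copies were set before their results were seen, and all others here after. Copies grouped by symbol number did not give equal counts. The 8 copies of iMet-CAT-1 had between 46 and 1797 counts summed over the control libraries. Ratios of knockdown to control within such groups lay closer together than in shuffled groups. Over 197 genes in 51 such groups, the SD of log2 ratios within a group was 0.22, against a median of 0.31 when ratios were shuffled within families (permutation p = 0.0004, 10000 permutations). Reads shared among identical copies may therefore tie their ratios together, or the copies may be regulated alike, which these counts do not separate. The family explained 44.3% and 48.6% of the variance of the log2 ratio of number 4 to number 3 in control and knockdown, and 29.97% and 33.6% of the ratio of knockdown to control in numbers 3 and 4, so most of the variance lay within families. Shuffled families gave a median near 10.3% (permutation p = 1e-05 in each, the smallest 100000 permutations give). The shuffling treats genes as independent, while copies within a family may share reads. The p therefore does not separate read sharing from a change of whole families. Ser-ACT-1-1, an A34 gene outside the 8 families in an intron of POM121L2, took 0.996% and 0.319% of control counts in numbers 3 and 4, and 1.05% and 0.328% in knockdown, with family-level TMM-scaled log2 ratios of −0.03 and 0.19. It was singled out after its values were seen.

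The libraries of replicate numbers 3 and 4 differed far more than the groups. The difference was not confined to a few dominant genes. With the 10 most abundant removed, the other 479 tested genes had a median absolute log2 ratio of 1.08 between numbers. Depth alone would not leave differences in both directions after scaling. Summed totals differed by 1.45-fold between numbers, a log2 ratio of 0.53. Of 41 tested families with at least 1000 counts in every library, 16 were higher and 11 lower in number 4 by more than this after scaling (edgeR adjusted p under 0.05). Both checks were set after the calls between numbers were known. They describe the difference and are no separate tests of it. A batch of library preparation, size selection or culture marked by the number may underlie the first component, with 90.4% of the variance, and cannot be told apart from other sources because no label describes the numbers. No biological explanation was tested.

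The larger share of A34 families in knockdown cells was seen in both numbers. A fall of the families listed as sources of tRNA fragments could raise all other shares. Val-AAC is on both lists. Among counts outside the fragment sources, however, the other 7 A34 families together were still higher by 4.17 and 3.28 percentage points in numbers 3 and 4. They took 13.6% and 14.3% of these counts in control, against 17.7% and 17.5% in knockdown. With Val-AAC kept and the other fragment sources removed, all 8 were higher by 4.47 and 2.78. These points are of a smaller total, so their size cannot be set against the points of all counts. A rise of all tRNAs of the same 8 amino acids stays open, since the share of their other anticodons was higher by 2.85 and 2.02 points. Relative to their control share, that rise was smaller than the rise of the A34 families. The log2 ratio of A34 family to other anticodons of its amino acid was higher in 5 of 8 amino acids (mean 0.23 ± 0.11 SE, two-sided exact sign-flip permutation p = 0.0938), with 0.64 and 0.91 for arginine but −0.09 and −0.00 for serine. A loss of reads with inosine in control cells, where it is read as a mismatch, also stays open: the ratio was higher in both numbers for 4 of 8 amino acids and lower beyond counting error in both for 0. An effect of ADAT2 on the abundance of these tRNAs is untested and open as well. Any other difference between the edited and the control line cannot be told apart from it by this design.

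Met-CAT-5-1 and Met-CAT-chr6-167 together had 252 and 276 counts in control libraries 3 and 4, against 1059 and 935 in knockdown. A shift of reads from the other 10 elongator Met genes is argued against, since their summed log2 ratio was 0.154 and −0.0163 in numbers 3 and 4. A gain of the chromosome 6 segment is argued against by 17 other tested tRNA genes within 100 kb, whose median log2 ratios were 0.12 and 0.25. They are not independent readings, since several are copies that may share reads. Some had few counts, such as a mean of 8.5 for Ala-AGC-10-1. Of these 17, Ala-AGC-9-1 and Ala-AGC-9-2 rose with the replicate number as a term, while Met-CAT-4-1 between them and the abundant Ile-AAT-6-1 had ratios of 0.06 and −0.07, and 0.12 and 0.08. An effect of the ADAT2 difference on these genes stays open, as untested. So does any other difference between the edited and the control line, which this design cannot tell apart from it.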
